A study of Mus musculus with 16 samples.

How the data were processed

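RNA was sequenced from oligodendrocytes of 16 juvenile OF-1 mice, an outbred strain. The cells were taken from dissociated brains by magnetic sorting for the O4 surface antigen. The labels place 4 libraries in each of 4 groups, male control, female control, male BPA and female BPA. Exposed pups received bisphenol A (BPA) through the water their mothers drank, from gestational day 7 through lactation, and brains were taken at postnatal day 16. The labels give the dose as 40 µg/kg/day, and the study's design text gives 250 µg/mL in the water. Both hold together only at an intake of 0.16 mL of water per kg per day, so the dose is printed as labelled and its scale was not settled. The study had 9 control and 10 exposed mice, of which 16 gave RNA. Per the study's design text each library is from a separate sample. Neither litter nor batch is labelled, and the p-values measure the spread between these libraries. As BPA was given to the mothers, littermates share their exposure. Some mice of a group may be littermates, so p-values for BPA against control may be too small.

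Per the labels' protocols, stranded poly(A) libraries were made from 100 ng of RNA. Per the submitters' processing notes, the authors used bcl2fastq 2.20.0.422, STAR 2.5.3a, HTSeq 0.6.1p1 and DESeq2 1.16.1 with the mouse build mm39. The deposited table holds whole-number counts per gene and library, and beside them values normalized by the authors, which were not used here except to check that they equal the counts divided by median-of-ratios size factors. Its layout could not be read by the automated check of units, so the counts were described from their values alone and not independently checked. For that reason edgeR was not used for any result given here, although its quasi-likelihood test had been fixed as the main test before the data were examined, and limma-voom took its place. A run of that test outside the scripts was looked at. The table has 32207 genes, of which 31717 have a symbol in GENCODE release M21. That release was used only for symbols, chromosomes and transcript sequences, and no coordinates are printed.

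Genes were kept for testing with a minimum count of 10 in enough libraries for the smallest group and 15 in total, which left 16339 genes and 99.947% of the counts. Libraries were scaled by trimmed mean of M values (TMM), computed by a re-implementation in R 4.3.3. limma 3.58.1 fitted all 16 libraries with 1 coefficient per group (voom weights, robust empirical Bayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests are two-sided. The contrasts were BPA against control in males, in females and as the mean over both sexes, the difference of those effects between the sexes, and females against males within each exposure. Levels are CPM (a gene's counts relative to the scaled library total) ± SD, and log2 fold changes carry their SE.

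Before the data were examined, 30 gene lists were fixed, and 29 were tested with camera on log2 CPM (prior count 2, preset correlation 0.01). They cover oligodendrocyte stages (precursor, committed and newly formed, myelinating), other cell types (microglia, astrocyte, neuron, endothelial, mural and fibroblast, ependymal and choroid plexus, blood cells) and processes (cholesterol biosynthesis, fatty acid and sphingolipid synthesis, immediate early and dissociation response, cell cycle, interferon response, inflammatory mediators, unfolded protein and integrated stress response, antioxidant response, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, nuclear receptors, thyroid hormone signalling, estrogen response, glucocorticoid response, glutamate and GABA receptors, chromatin modifiers, xenobiotic metabolism, circadian clock). The remaining list holds sex-chromosomal genes that check the labels. Beside each preset result stand camera with an estimated correlation and fry, and an exact permutation test of list means that was added later. The genes named were set by a rule fixed in advance: called genes with a mean of at least 1 CPM and a full symbol, the 5 smallest p where fewer than 3 were called, up to 4 members of each list by smallest p, and always 7 genes, among them Mbp, Mog, Pdgfra, Esr1, Esr2 and Thra. The results of 3 genes that the rule selects are not reported here. Xlr3b and 1700063D05Rik lie outside the rule and were named because only 3 genes were called. Esr2 was below the filter.

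Total counts ranged from 23603816 to 42575326 per library. A gene with 0 counts could reach 3 counts, or from 0.0705 to 0.127 CPM, by counting error alone. For 8932 genes above 10 CPM, 96.1% of the 95% confidence intervals in males spanned less than 2-fold either way. On simulated counts for males, limma-voom recovered 62.7% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 5 unchanged genes called among 16339. For both sexes combined these shares were 77.6%, 89.6% and 95.5%, with 7 unchanged genes called. The changed genes were drawn from those with a mean above 2 CPM, so these shares do not cover genes at lower levels. A list lowered by a simulated log2 shift of -0.3 in males was called by camera with the preset (adjusted p 2.94e-06) and with the estimated correlation (0.00272), and no unchanged list was called. Simulated genes varied independently of each other, while members of the precursor list had an estimated correlation of 0.502 in the data. The simulation therefore cannot tell how often lists of correlated genes are falsely called or missed.

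Alternatives covered the low-count filter, scaling, sample quality weights, limma-trend, a replicate block, covariates, the libraries in the fit, and leaving out each library in turn. Chromatin accessibility was measured in the same study and is not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.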

Results

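Gene expression was measured by RNA sequencing in O4-sorted brain oligodendrocytes of 16 mice at postnatal day 16, 4 in each group of sex and BPA exposure. Total counts averaged 31520000 ± 4970000 in male controls, 39870000 ± 2510000 in female controls, 35590000 ± 3780000 in BPA males and 32340000 ± 7060000 in BPA females (SD, n = 4 each). Female controls had higher totals than male controls by an exact permutation test (p = 0.0286, the smallest that 4 against 4 can give), but not after Benjamini-Hochberg adjustment (0.343). Mbp, which encodes myelin basic protein, stood at 18390 ± 1440 CPM in male controls and 17790 ± 1690 CPM in female controls (SD, n = 4). Xist and Y-linked counts matched the labelled sex in 16 of 16 libraries. Between mice of the same group, chi-square per gene against counting noise was from 16.0 to 32.7 in 21 of 24 pairs, and 87.9, 104.8 and 131.9 in the 3 pairs with male BPA 2.

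Among the 1000 most variable genes, principal component 1 held 18.4% of the variance and separated the sexes (permutation p = 0.000155, adjusted 0.00124). X- and Y-linked genes were not left out of this set, and Xist had a log2 fold change of 12.1 between control females and males. The separation can therefore rest on such genes and does not show a sex difference in autosomal genes. Component 3 held 12.5% and differed with exposure, with mean scores of -8.83 in controls and 8.83 in BPA libraries (permutation p = 0.0014, adjusted 0.0056). Littermates share their exposure and are not labelled, so this p may be too small. Female BPA 3 was the exception among BPA libraries, at -11.32, below 5 of the 8 controls.

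**Figure D1:**
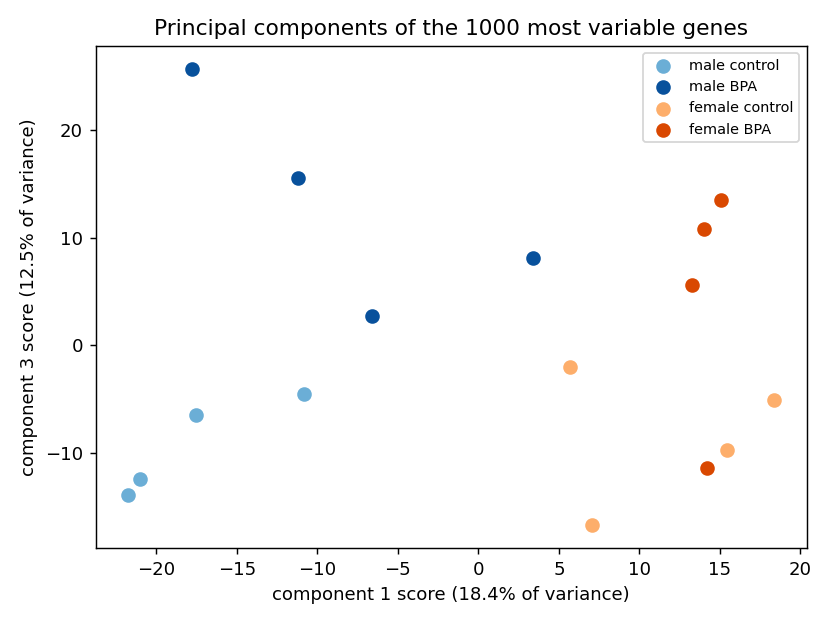
Scores of the 16 libraries on principal components 1 and 3 of the 1000 most variable genes, with X- and Y-linked genes not left out, 1 point per library, coloured by group. Component 1 (18.4% of the variance) parts males from females, and component 3 (12.5%) has a mean of -8.83 in controls and 8.83 in BPA libraries, with female BPA 3 among the controls.

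In males, the question was which oligodendrocyte genes differ after early BPA exposure. Limma-voom called 1 gene in this comparison, while 1300 of 16339 genes (7.96%) had an unadjusted p under 0.05. No gene was called when any 1 of the 8 male libraries was left out. The genes given here were not called. Pcdhga5, an adhesion protein of the gamma protocadherin cluster, had a log2 fold change of 1.60 ± 0.25, and Plk5, a polo-like kinase, one of -1.47 ± 0.24 (limma-voom adjusted p 0.079 for both). Rpp30, a subunit of RNase P, was at -0.78 ± 0.15 and Gpcpd1, a glycerophosphodiesterase of choline metabolism, at -0.52 ± 0.10 (limma-voom adjusted p 0.221 for both). Pcdhga5 shares 45.3% of its 50-base transcript words with other genes, so its counts are uncertain. It was at 1.06 to 1.68 CPM in male controls and 3.05 to 6.07 CPM in BPA males. Female controls had 2.61 to 4.29 CPM and BPA females 3.2 to 4.2 CPM, so the male controls also lay below the female controls.

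Of the myelin genes, Mbp and Mog were not called in males. The myelinating oligodendrocyte list was higher in 22 of 29 members (median log2 fold change 0.06) and was not called by camera with the preset (adjusted p 0.0724). Log2 fold changes were -0.12 ± 0.12 for Mbp and 0.20 ± 0.11 for Mog, which encodes a surface myelin glycoprotein (limma-voom adjusted p 0.858 and 0.706). Among earlier stages, Pdgfra, the growth factor receptor of precursors, had -0.43 ± 0.23 (165.9 ± 37.8 against 121.8 ± 18.4 CPM, limma-voom adjusted p 0.681). Thra, a thyroid hormone receptor, had -0.13 ± 0.08. Esr1, an estrogen receptor that BPA can bind, was near the detection limit at 0.243 ± 0.0376 CPM in control and 0.249 ± 0.164 CPM in BPA males.

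Of the 29 lists, camera with the preset correlation called 8 in males, 3 lower and 5 higher. The precursor list was lower in 16 of 17 members (median log2 fold change -0.28, camera adjusted p 2.13e-05, 0.935 with the estimated correlation). Among its members Tnr, an extracellular matrix protein, had -0.47 ± 0.16 and Sox6, a transcription factor of precursors, -0.41 ± 0.15. The committed and newly formed oligodendrocyte list was lower in 13 of 15 (median -0.26, camera adjusted p 1.26e-06, estimated 0.935), and 5 of its members passed adjusted over the list alone. Bcas1, a marker of early myelination, went from 1122 ± 70.4 to 916.5 ± 95.5 CPM, and Fyn, a kinase of myelination onset, from 915.7 ± 80.1 to 676.9 ± 68.9 CPM (SD, n = 4). The glutamate and GABA receptor list was lower in 20 of 28 (median -0.20, camera adjusted p 0.00732, estimated 0.935), with Grik2 at -0.30 ± 0.08. The glucocorticoid response list was higher in 11 of 12 (median 0.22, camera adjusted p 0.00174, estimated 0.280). Within it Pdk4, a kinase that restrains glucose oxidation, had 0.66 ± 0.17, and 4 members passed adjusted over the list alone. The other lists called higher were nuclear oxidative phosphorylation (61 of 74 members higher, median 0.05, camera adjusted p 0.00196), microglia (15 of 15, 0.39, 0.00473), mural and fibroblast (10 of 11, 0.65, 0.0112) and ependymal and choroid plexus (8 of 10, 0.57, 0.0287). All 4 had an adjusted p of 0.935 with the estimated correlation. No list passed in males by camera with the estimated correlation or by fry. In the exact permutation test of list means the precursor and committed lists had p = 0.0286, the smallest that 4 against 4 can give, so this test could hardly pass after adjustment over 29 lists.

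Male BPA 2 had an astrocyte list mean of 8.66 log2 CPM, against 5.90 to 7.33 in the other 15 libraries. Without it the median log2 fold change in males was 0.28 for the mural and fibroblast list and 0.33 for the ependymal and choroid plexus list, neither of them called by camera, and -0.365 for the glutamate and GABA receptor list. With each of the 8 male libraries left out in turn, the precursor (-0.35 to -0.20), committed and newly formed (-0.29 to -0.20) and glucocorticoid response lists (0.185 to 0.33) stayed called by camera with the preset. The glutamate and GABA receptor call was lost without male BPA 3, and its median was -0.08 without male BPA 1. The microglia call was lost without male control 1 or 4 or male BPA 3 (medians 0.22 to 0.64), and the nuclear oxidative phosphorylation call without male control 2 or 4 or male BPA 3 (0.01 to 0.11). The mural and fibroblast call was lost without male control 3 too, and the ependymal and choroid plexus call without male control 2 or 3 or male BPA 1 or 3 (median 0.86 without male BPA 4).

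**Figure D2:**
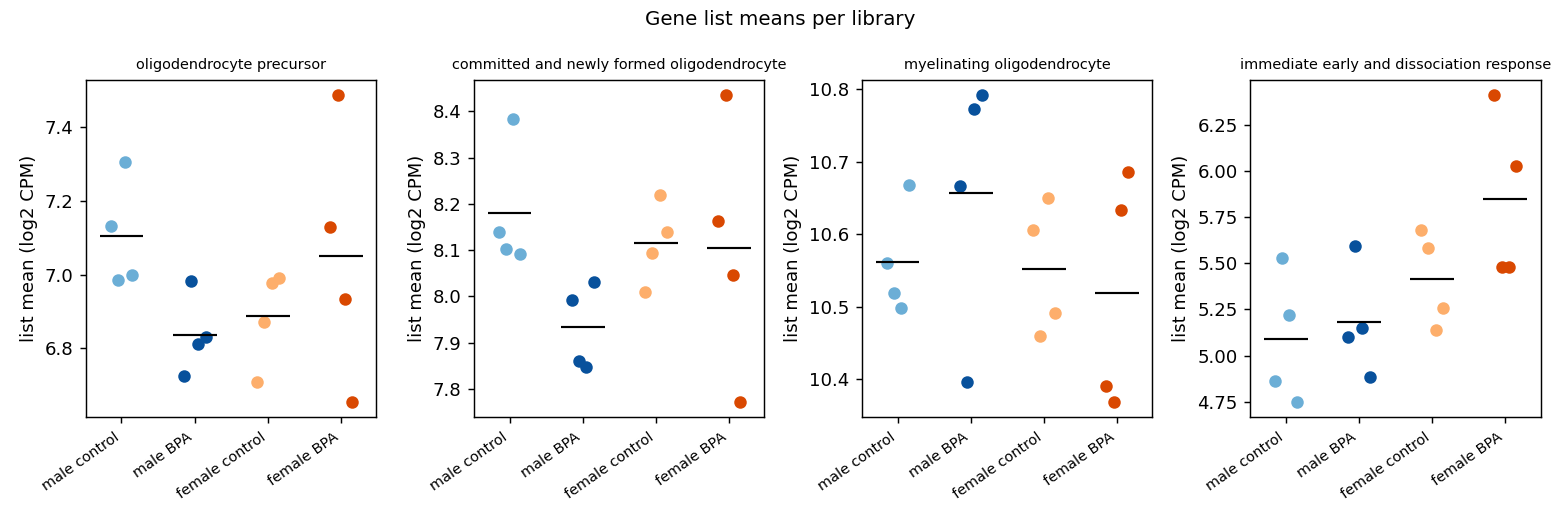
Mean log2 CPM of the members of 4 gene lists in each library, 1 point per library, with a bar at the group mean (n = 4). BPA males lie below male controls in the precursor list, whose group means are 6.84 and 7.11.

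In females, the same question was asked of the BPA and control groups. Pde9a, a phosphodiesterase that degrades cGMP, had the smallest p, with 28.6 ± 7.45 CPM in controls and 7.85 ± 6.28 CPM with BPA (SD, n = 4) and a log2 fold change of -2.23 ± 0.40, but was not called (limma-voom adjusted p 0.648). Utp14b, a nucleolar protein of ribosomal RNA processing, had -0.53 ± 0.11, and Tbcc, a cofactor of tubulin folding, -0.42 ± 0.09. Ddit3, the stress transcription factor CHOP, had 0.54 ± 0.11, and Dnajb4, a heat shock co-chaperone, 0.27 ± 0.06 (limma-voom adjusted p 0.648 for each of these). No gene was called by limma-voom in females, and 744 (4.55%) had an unadjusted p under 0.05. Mbp was at -0.03 ± 0.12, Mog at 0.02 ± 0.11, Pdgfra at 0.33 ± 0.23, Thra at -0.08 ± 0.08 and Esr1 at -0.10 ± 0.46 on the log2 scale. Pdgfra was at 233 CPM in female BPA 2, and its log2 fold change was 0.10 without that library, 0.20 without female control 1 and 0.51 without female BPA 4.

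Camera with the preset called 5 lists in females. All 24 cholesterol biosynthesis genes were lower (median -0.14, camera adjusted p 1.61e-08, estimated 0.661), among them Mvk, mevalonate kinase, at 135.5 ± 8.35 against 110.8 ± 13.0 CPM. The immediate early and dissociation response list was higher in 22 of 23 (median 0.42, camera adjusted p 1.5e-06, estimated 0.661), with the transcription factor Egr2 at 0.85 ± 0.37. The unfolded protein and integrated stress response list was higher in 17 of 18 (median 0.10, camera adjusted p 6.9e-06, estimated 0.661). Its members Ddit3, Hspa5, Sesn2 and Herpud1 passed adjusted over the list alone, and Hspa5, the chaperone BiP, went from 442.1 ± 32.4 to 611.7 ± 34.9 CPM (SD, n = 4). Inflammatory mediators were higher in 12 of 14 (median 0.43, camera adjusted p 0.000218, estimated 0.661), with the chemokine Cxcl2 at 1.06 ± 0.30 as the 1 member that passed adjusted over the list alone. The precursor list was higher in 16 of 17 (median 0.16, camera adjusted p 0.00984, estimated 0.975). No list passed in females with the estimated correlation or by fry, and the exact permutation test, with 0.0286 as its smallest possible p, could hardly pass after adjustment over 29 lists. The microglia list was not called in females (median 0.07, camera adjusted p 0.576). Across the 16 libraries with group means taken out, its mean had a Pearson r of 0.92 with that of the inflammatory mediators and 0.89 with that of the immediate early list (permutation, Benjamini-Hochberg adjusted p 6e-05 for both; 0.88 and 0.81 without female BPA 1 and male control 2), a test chosen after the values were seen. Female BPA 1 had the highest microglia mean (6.91 log2 CPM) and immediate early mean (6.41). It also had a mean of 2.95 log2 CPM for inflammatory mediators, against 1.83 to 2.01 in the other BPA females and 1.3 to 2.01 in female controls. Without it the median log2 fold change of that list was 0.13 and the camera call was lost, as it was without female control 3, and the median of the immediate early list was 0.19. The precursor median was 0.006 without female BPA 2 and 0.32 without female BPA 4, and its call was lost without female BPA 2 or female control 1. Across the 16 libraries with group means taken out, the cholesterol biosynthesis and precursor list means had a Pearson r of -0.65 (permutation p 0.0249, Benjamini-Hochberg adjusted 0.0415 over 5 pairs of lists) and a Spearman rho of -0.59 (adjusted 0.0792), and r was -0.52 without female BPA 2 and 4. With each of the 8 female libraries left out in turn, the cholesterol biosynthesis (medians -0.20 to -0.085), immediate early (0.19 to 0.59) and unfolded protein and integrated stress response lists (0.05 to 0.20) stayed called.

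With both sexes combined, Utp14b (ENSMUSG00000079470, chromosome 1) fell from 73.7 ± 6.11 CPM in 8 controls to 51.4 ± 6.20 CPM in 8 BPA libraries (SD), a log2 fold change of -0.53 ± 0.08 (limma-voom adjusted p 0.0324). Its fold change was -0.53 in each sex, and 8 of 8 BPA libraries (43.1 to 60.4 CPM) lay below all 8 controls (64.0 to 83.5 CPM). Of its transcript words 2.23% occur in other genes, most of them in Acsl3, and Acsl3 itself was at -0.11 ± 0.06. The unnamed transcript 1700063D05Rik (chromosome 9) fell by 1.53 ± 0.21 on the log2 scale at a mean of 0.487 CPM (limma-voom adjusted p 0.0324). Xlr3b, of an X-linked lymphocyte-regulated family, rose by 1.77 ± 0.27 at a mean of 0.656 CPM (limma-voom adjusted p 0.0414), but 56.5% of its transcript words occur in other genes, so its counts are uncertain. These were the 3 genes called, and 1256 (7.69%) had an unadjusted p under 0.05. No gene was called by limma-voom when male control 1, 3 or 4, female control 1 or 2, male BPA 1, 3 or 4, or female BPA 1 or 2 was left out, nor with the stricter filter, with the replicate block or without both male BPA 2 and female BPA 1.

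**Figure D3:**
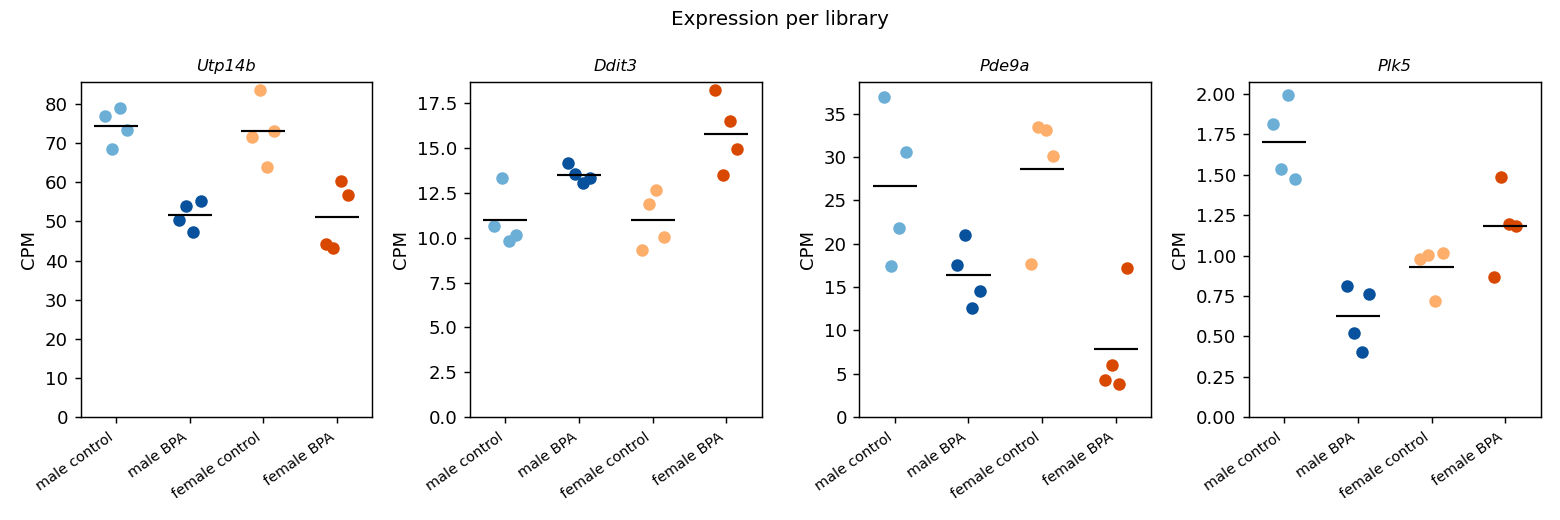
CPM of Utp14b, Ddit3, Pde9a and Plk5 in each library, 1 point per library, with a bar at the group mean (n = 4). Utp14b lies lower in all 8 BPA libraries than in all 8 controls.

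Camera with the preset called 9 lists over both sexes. The unfolded protein and integrated stress response list was higher in 16 of 18 (median 0.07, camera adjusted p 0.000272, estimated 0.690). It was also the list in which fry's mixed test found change in either direction (adjusted p 0.0325). Fry's directional test (adjusted p 0.311) and the exact permutation test of list means (adjusted p 0.592) did not call it. Ddit3 (10.98 ± 1.46 against 14.66 ± 1.83 CPM), Herpud1, Sesn2 and Hspa5 passed adjusted over the list alone (n = 8). The glucocorticoid response list was higher in 10 of 12 (median 0.16, camera adjusted p 0.00112, estimated 0.264), where Pdk4, Per1 and Fkbp5 passed adjusted over the list alone. Immediate early genes (median 0.26, camera adjusted p 0.00112), inflammatory mediators (0.28, 0.00769), microglia (0.24, 0.0127), mural and fibroblast (0.36, 0.0178) and ependymal and choroid plexus genes (0.44, 0.00769) were also called higher. Committed and newly formed oligodendrocyte genes (median -0.13, camera adjusted p 0.00112) and cholesterol biosynthesis genes (-0.06, 0.00646) were called lower. These 7 lists had an adjusted p of 0.936 with the estimated correlation, by which no list was called. With each of the 16 libraries left out in turn, camera with the preset still called the unfolded protein and integrated stress response (medians 0.03 to 0.125), glucocorticoid response (0.15 to 0.22), immediate early (0.12 to 0.35) and committed and newly formed lists (-0.15 to -0.05). The cholesterol biosynthesis call was lost without male BPA 2, female BPA 1 or female BPA 2 (median -0.03 without the last) and the ependymal and choroid plexus call without male control 2 or female control 3. The inflammatory mediator call was lost without male control 1 or 4, female control 3 or female BPA 1 (median 0.155 without the last). The mural and fibroblast call was lost without male control 3, female control 3, male BPA 2 (median 0.17) or female BPA 1 or 4. The microglia call was lost without male control 1 or 4, female control 3 or 4, male BPA 1 or 3 or female BPA 1 (median 0.09 without the last). The other 20 lists were not called. Their median log2 fold changes were -0.04 for precursor, -0.001 for myelinating, -0.03 for fatty acid and sphingolipid synthesis, 0.14 for astrocyte, -0.095 for neuron, -0.005 for endothelial and 0.08 for blood cell genes. For processes they were -0.01 for cell cycle, 0.03 for interferon response, 0.02 for antioxidant response, 0.02 for nuclear oxidative phosphorylation, 0.04 for mitochondrially encoded genes, -0.005 for cytosolic ribosomal proteins and 0.05 for nuclear receptors. The last were 0.01 for thyroid hormone signalling, 0.02 for estrogen response, 0.05 for glutamate and GABA receptors, 0.004 for chromatin modifiers, 0.06 for xenobiotic metabolism and -0.02 for circadian clock genes. Median, mean and test differ in sign here for the myelinating, endothelial, cell cycle, glutamate and GABA receptor, chromatin modifier and circadian clock lists.

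The interaction asked whether the BPA effect differs between the sexes. Plk5 had the smallest p, with a female minus male difference of 1.80 ± 0.33 on the log2 scale, but was not called (limma-voom adjusted p 0.878). Pdgfra had 0.75 ± 0.32 (limma-voom adjusted p 0.999), and 0.53 without female BPA 2. Dzip3, a ubiquitin ligase, had 0.42 ± 0.08, Triobp, an actin-bundling protein, -0.37 ± 0.08, Pcdhga5 -1.53 ± 0.32 and Rps3a3, a ribosomal protein copy that shares 65.1% of its words, -6.80 ± 1.48, none of them called. Plk5 was at 1.48 to 1.99 CPM in male and 0.717 to 1.01 CPM in female controls, and Pcdhga5 at 1.06 to 1.68 and 2.61 to 4.29 CPM. Rps3a3 was at 0 to 0.059 CPM in 3 male controls and 13.3 to 29.3 CPM in female controls. The differences of these genes therefore rest in part on unlike controls. No gene was called by limma-voom, and 772 (4.72%) had an unadjusted p under 0.05. Camera with the preset called 11 lists. The precursor list had a median difference of 0.50 (above 0 in 16 of 17 members, camera adjusted p 7.88e-08). Its mean was 7.11 log2 CPM in male controls and 6.89 in female controls. The committed and newly formed list had a median difference of 0.33 (1.71e-05) and the cholesterol biosynthesis list one of -0.16 (5.59e-06). The others were glutamate and GABA receptors (0.29), nuclear oxidative phosphorylation (-0.07), cell cycle (0.22), myelinating oligodendrocyte (-0.13), immediate early genes (0.31), cytosolic ribosomal proteins (0.10), mitochondrially encoded genes (-0.13) and inflammatory mediators (0.29). With the estimated correlation each of the 11 had an adjusted p of 0.820, and the exact permutation p of the precursor list was 0.0502 (adjusted 0.921). With each of the 16 libraries left out in turn, the precursor (medians 0.37 to 0.65), committed and newly formed (0.21 to 0.48), cholesterol biosynthesis (-0.205 to -0.09) and glutamate and GABA receptor lists (0.18 to 0.45) stayed called by camera with the preset, with the value nearest 0 without female BPA 2 for each of them. The nuclear oxidative phosphorylation call was lost without male control 4 or male BPA 3 (medians -0.12 to -0.025) and the cell cycle call without female BPA 1 or 2 (0.12 to 0.37). The myelinating oligodendrocyte call was lost without female control 3, male BPA 3 or 4 or female BPA 1 or 2 (-0.21 to -0.07). The immediate early call was lost without male control 2 or 3, female control 4, male BPA 4 or female BPA 1 or 4 (0.07 to 0.515). The inflammatory mediator call was lost without male control 2 or 3, female control 3, male BPA 2 or 4 or female BPA 1 or 4 (-0.04 to 0.49, with the lowest without female BPA 1). The ribosomal protein call was lost without male control 1 or 3, female control 3 or 4, male BPA 2 or 4 or female BPA 1 or 2 (0.06 to 0.15). The mitochondrially encoded call was lost without male control 2 or 4, female control 2 or 4, male BPA 1 or 3 or female BPA 1 or 4 (-0.23 to -0.04).

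The effects in males and females correlated weakly across 16339 genes (Pearson r 0.268, Spearman rho 0.140), which are not independent replicates. The jackknife SE of r over the 16 libraries was 0.168, and r was 0.168 without male BPA 2, 0.171 without female control 4, 0.142 without male BPA 2 and female BPA 1, and 0.03 with no low-count filter. At an unadjusted p under 0.05 in both sexes, 40 genes were higher in both (11.1 expected if genes were independent), 66 lower in both (18.9) and 20 opposite (29.3). Genes are not independent, and these counts were not set against other splits of the libraries. The correlation of 0.268 was reached in 7 of 100 such splits. No gene was called in both.

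Females were compared with males within each exposure to see baseline sex differences. In controls, Xist, the RNA that silences an X chromosome, was at 824.8 ± 75.0 CPM in females and 0.173 ± 0.0149 CPM in males, and Ddx3y, a Y-linked RNA helicase, at 0.0766 ± 0.0241 and 110.7 ± 7.95 CPM (SD, n = 4). Of 9 genes called, 8 were sex-chromosomal (Xist, Eif2s3x, Ddx3y, Uty, Kdm5d, Eif2s3y, Uba1y and Gm29650). Among BPA libraries, 8 genes were called and all were sex-chromosomal, with Ddx3x in place of Eif2s3x.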

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

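All tests of explanations in this part were chosen after the pattern was seen, except the other cell type covariate and the splits of the libraries.

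Camera with the preset called the precursor and committed oligodendrocyte lists lower in BPA males, and the sorted cells may have held a smaller share of these early stages. Both calls were lost with the estimated correlation (adjusted p 0.935), and 0 of 17 precursor genes and 5 of 15 committed genes passed adjusted over the list alone. The median log2 fold change of the precursor list in males was -0.277. With the first component of other cell type markers as a covariate it was -0.276, and the committed median went from -0.261 to -0.222. This component therefore does not account for the lower precursor median. It held 47.3% of the variance of these markers, and camera with the preset called microglia genes higher in the same males. Cells of other types in the sort are thus not excluded as a whole. Across the 16 libraries with group means taken out, the precursor mean fell as the myelinating mean rose (Pearson r -0.66, permutation p 0.0141, adjusted 0.0352; Spearman rho -0.65, p 0.0229, adjusted 0.0572, 5 pairs of lists tested). Without the 2 farthest libraries, female BPA 2 and 4, r was -0.53. A candidate explanation is therefore that stage shares vary between animals, and neither litter nor an effect of BPA on maturation was tested.

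In male BPA 4 the Y-linked genes stood higher than in the other 7 males, with Ddx3y at 250 CPM against 108 ± 11.7 CPM and Kdm5d at 78.8 against 35 ± 2.93 CPM (SD, n = 7). RNA of other males mixed in is argued against, since mixing cannot lift a gene above its highest source and 5 of 6 genes stood at 1.54 to 2.1 times the highest other male (median of all 6, 1.8). The exception was Gm47283, at 0.564. The lowest ratio had been the first form of this test, and the median took its place after 0.564 was seen. BPA exposure is argued against too, because the same genes had a median log2 ratio of -0.07 in male BPA 1 to 3 against male controls. An extra copy of the Y-linked genes in this animal stays open. Their median log2 ratio to the other males was 1.09, which restates the pattern and does not support it, and that of 287 X-linked genes was 0.029. DNA was not analysed here.

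Camera called 11 lists for a difference of the BPA effects between the sexes, given as median female minus male log2 differences, and each of the 11 had an adjusted p of 0.820 with the estimated correlation. The medians were 0.50 for precursor, 0.33 for committed and newly formed, -0.13 for myelinating oligodendrocyte, -0.16 for cholesterol biosynthesis and 0.29 for glutamate and GABA receptor genes. They were -0.07 for nuclear oxidative phosphorylation, -0.13 for mitochondrially encoded, 0.22 for cell cycle, 0.10 for cytosolic ribosomal protein, 0.31 for immediate early and 0.29 for inflammatory mediator genes. Without female BPA 2 they were 0.367 for precursor, 0.206 for committed and newly formed and -0.07 for myelinating genes, and without female BPA 1 -0.041 for inflammatory mediators.

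List means, levels of genes named here and library measures were examined in each of the 4 groups, in 352 tests of 4 libraries. In 25 of them (7.1%) a library lay far from the other 3. Chance gives about 1 in 20 for independent, normally distributed values. These measures overlap and many genes were picked by their values, so 7.1% cannot be weighed against that share. Male BPA 2 had the highest astrocyte list mean (8.66 log2 CPM against 5.90 to 7.33 in the other 15 libraries) and stood apart in glutamate and GABA receptor genes (list mean 3.64 log2 CPM), circadian clock genes (5.08), Col1a2 (25.4 CPM), Cxcl2 (5.28 CPM) and Tmem163 (351 CPM). Female BPA 1 did so in microglia (6.91) and inflammatory mediator genes (2.95 log2 CPM), C1qa (240 CPM) and Ddx3y (1.33 CPM). The Y-linked Eif2s3y (1.13 CPM), Kdm5d (0.549 CPM) and Uty (0.434 CPM) were also higher in it than in the other females. There these genes and Ddx3y reached at most 0.106 CPM. The cause was not tested. Rps3a3 stood at 13.6 CPM in male control 2, 29.3 CPM in female control 1 and 30.2 CPM in female BPA 4. Female BPA 4 also stood apart in Pde9a (17.2 CPM) and Triobp (39 CPM), and Pcdh15 in male BPA 4 (31.2 CPM) and female BPA 2 (38.7 CPM). Female control 4 stood apart in interferon response genes (1.65 log2 CPM), Per1 (97.8 CPM) and Mvd (178 CPM). Female control 3 was low in inflammatory mediators (1.3), glucocorticoid response (4.74 log2 CPM) and Plk5 (0.717 CPM). The remaining ones were Pdgfra in female control 1 (86.6 CPM), mural and fibroblast genes in male control 3 (0.84 log2 CPM) and Maff in male control 2 (1.77 CPM).

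Other splits of the same libraries were fitted the same way. For the female against male difference in controls 1 of 35 splits, the real one, gave as many as 9 genes, and the highest other gave 3. This is the smallest share that 35 splits can give. Of the 9 genes 8 are sex-chromosomal. A split that mixes the sexes loses their difference, so the splits cannot decide about chance there. For the combined BPA effect 2 of 100 splits gave 3 genes or more, with 4 in the highest other. That share is under the 0.05 set in advance. With no correction over the 11 split tests, and with litters not labelled, it does not by itself exclude chance. No gene was called when any 1 of 10 of the 16 libraries was left out. Chance is not excluded for the 1 gene of the males (2 of 35 splits, highest other 1). With 0 genes called in females and in the interaction, any split gives as many (35 of 35 and 100 of 100, highest other 1 in each), so the splits say nothing there. As many as the 8 genes between females and males with BPA were called in 2 of 35 splits, so the count alone does not exclude chance, but all 8 are sex-chromosomal and Xist was at 875.5 to 992.7 CPM in BPA females and 0 to 0.349 CPM in BPA males. The highest other split, which exchanged male BPA 2 with female BPA 4, called 54 genes, and the cause of this was not tested. The list calls are no more than other splits give. As many lists were called in 27 of 35 splits for males (8, highest other 16), 30 of 35 for females (5, highest 15), 60 of 100 combined (9, highest 18) and 45 of 100 for the interaction (11, highest 17). The correlation of 0.268 between the sexes was reached in 7 of 100 splits, with 0.374 in the highest other.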

How the results depend on the processing

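Limma-trend, median-of-ratios scaling, the residual component, the fit without male BPA 2 and female BPA 1, the permutation of list means, and for lists both filters, the 8-library fit and the additive model were chosen after seeing the data. DESeq2's Wald test, edgeR with other size factors and a surrogate variable from svaseq had been planned and were not run. The 3 genes called over both sexes kept their direction in every alternative that gave them a value. The cause of the changes was not tested.

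In males, where 1 gene was called, 2 were called with no filter, 3 with limma-trend, 4 with only the 8 libraries, and 0 with quality weights, the marker component, the residual component, without male BPA 2 and female BPA 1, and without any 1 library (0 to 0). In females, where none was called, 2 were called with no filter and 1 with only the 8 libraries. Of the 3 genes over both sexes, 0 were called with the stricter filter, with the replicate block and without male BPA 2 and female BPA 1, and leaving out 1 library gave 0 to 5, with 5 without female control 4 and 1 without male control 2. The interaction gave 0 to 3 genes, with 3 without female control 4. Leaving out 1 library gave 4 to 9 genes between control females and males, with 4 or 5 without female control 1, 2 or 3. It gave 3 to 21 between BPA females and males, with 3 to 5 without any 1 BPA female and 21 without male BPA 2, and only the 8 BPA libraries gave 3.

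The replicate numbers do not pair the libraries, since 7 of 24 same-numbered pairs correlated above 0.1 (mean 0.0218) and 0 libraries correlated best with their own number. With the replicate block Pcdhga5 in males had an adjusted p of 0.016 by limma-voom. Lists called by camera fell to 0 in all 4 comparisons with the estimated correlation and with fry's directional test, while fry's mixed test called 1 over both sexes. The permutation of list means gave 0 too, but in males and females its smallest possible p of 0.0286 could hardly pass after adjustment over 29 lists, so it says nothing about stability there. Without male BPA 2 and female BPA 1, 14 lists were called in males and 3 in females, and the residual component gave 10 in females. Leaving out 1 library gave 6 to 14 lists in males (14 without male BPA 2), 4 to 11 in females (9 without female control 2, 10 without female BPA 3, 11 without female BPA 4), 5 to 10 combined (5 without female BPA 1) and 6 to 15 in the interaction (6 without female BPA 1). The correlation between the sexes was 0.03 with no filter, which adds genes of few counts, and 0.168 to 0.317 without 1 library.

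Of 1742 alternative values of 85 gene results, 20 reversed in 8 results, of Mbp, Mog, Pdgfra and Esr1, none of them called. Without male BPA 2 and female BPA 1, Mbp was at 0.011 in males, 0.002 in females and 0.007 combined, and in females Esr1 was at 0.005. With quality weights Mbp in females was at 0.001. Without 1 library the values in males ranged from -0.187 to 0.002 for Mbp and -0.543 to 0.182 for Esr1. In females they ranged from -0.084 to 0.028 for Mbp, -0.025 to 0.053 for Mog and -0.407 to 0.15 for Esr1. Combined they ranged from -0.163 to 0.039 for Pdgfra and -0.319 to 0.047 for Esr1. For the 8932 genes above 10 CPM, the 95% intervals in males reached a median of 0.18 to either side on the log2 scale, which limits what could be detected. Genes at lower levels, such as Esr1, are not covered by this value.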

Other observations

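Utp14b, which acts in ribosomal RNA processing, was lower with BPA by the same log2 fold change of -0.53 in males and females, and its 8 BPA libraries lay below all 8 controls. The gene was picked by its call on these same libraries, so neither observation is separate support for it. Its call over both sexes was lost with the stricter filter (limma-voom adjusted p 0.0721), with the replicate block (0.0879), without male BPA 2 and female BPA 1 (0.0965) and without any 1 of 11 libraries (0.056 to 0.133). Genes of the unfolded protein and integrated stress response, led by Ddit3, Herpud1, Sesn2 and Hspa5, had a list median above 0 in both sexes (0.07 in males and 0.10 in females on the log2 scale). The glucocorticoid response, led by Pdk4, had medians of 0.22 and 0.16. Camera with the preset called the first list in females but not in males (adjusted p 0.0724) and the second in males but not in females (0.143). With the estimated correlation neither was called, with adjusted p of 0.935 in males and 0.661 in females for the first and 0.280 and 0.809 for the second. The difference between the sexes was not called for either list (camera adjusted p 0.125 for both, 0.820 with the estimated correlation).

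Rps3a3, a ribosomal protein copy, was at 0, 0.0274 and 0.059 CPM in 3 male controls, between 11.9 and 16.5 CPM in 10 libraries and between 29.3 and 30.2 CPM in 3 libraries. Of 12961 autosomal genes with a mean of at least 1 CPM, 47 had from 2 to 14 libraries under a fraction of 0.05 of their highest library, among them Cwc22 and H2-Ab1. Such genes were chosen after their values were seen.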
